A study of Arabidopsis thaliana with 28 samples.

How the data were processed

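Poly(A) RNA was sequenced from cotyledons with the shoot apex and from hypocotyls of Arabidopsis thaliana Col-0 seedlings, dissected under a stereomicroscope after fixation in cold acetone, with the roots removed and dark samples handled under green safe light. The 28 libraries form 14 groups of 2 biological replicates (2 tissues, darkness and 6 times in light). Per the submitters' processing notes, reads were handled with CASAVA 1.8.2 and TopHat2 2.0.8, values came from Cuffnorm (no version given) and tests from Cuffdiff 2.1.1, and the genome build named is TAIR10, whose role is not given. The titles of the libraries call them stranded while the kit named is TruSeq v2, and the use of strand in counting is not given in the sources used here, so that the values of genes that overlap another gene on the other strand are uncertain.

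The deposited table of values holds FPKM, which the authors obtained from Cuffnorm, for 33557 genes in 28 libraries. The second deposited table holds the authors' Cuffdiff log2 fold changes and q-values for 12 comparisons of light with darkness. The deposited log2 fold and q-value columns were compared with the tests below and were not used in them. No pair of libraries held identical values (0 pairs). A reference annotation, TAIR10.1, matched 32810 of the loci and left 747 without a match. It gave exon lengths, positions (counted from 1) and, from its exons, the share of each gene's 50-nt stretches that also occur in another gene. This share counts either strand and includes genes that overlap at the same position. The build of the deposited values may differ.

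Depth was estimated from the steps between low FPKM values, since no read counts were analysed here. In 2129 genes of low level, 16352 values that came to 2 to 5 reads lay within 0.1 of a whole number in 88.0% of cases, against 20.0% for values spread evenly. Among 7041 nuclear coding genes of at least 500 nt and a mean of at least 20 FPKM, 125 were listed at 0 in 1 library of a pair and 55 in both, and 6 housekeeping genes had 0 such values. The SD between replicates on the log2 scale had a median of 0.141 in 17647 nuclear coding genes of at least 500 nt, 0.913 in 457 nuclear genes under 500 nt, 0.925 in 113 organelle genes and 0.216 in 461 others.

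Values were transformed to log2(FPKM + 1), and genes with a mean under 1 FPKM over the libraries were left out, which left 18678. One linear model with a mean for each of the 14 groups (14 residual degrees of freedom) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend and robust estimation), and 21 contrasts were tested, with p values adjusted by Benjamini-Hochberg within each contrast. A gene was called at an adjusted p under 0.05 and a change of at least 1. The contrasts were light against darkness at 6 times in each tissue, the difference between these changes (hypocotyls minus cotyledons) at 6 times, hypocotyls against cotyledons in darkness, and 6 h against 1 h in each tissue. Figures and annotation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

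The 30 gene lists, written before the data were examined, held 508 members, of which 461 passed the filter. They were tested with camera of limma at a preset correlation between genes of 0.01 and, beside it, with a correlation estimated from the data, adjusted over all lists and contrasts of a kind. Of 348 tests of light against darkness, 201 were called with the preset correlation and 32 of these also with the estimated one. Of 174 tests of the difference between tissues the counts were 61 and 4, and of 29 tests in darkness 16 and 0. Counts of members called over all genes differed from counts adjusted over the list alone in 16 cases, by at most 4 members.

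The genes named were chosen by a rule written before the data were examined, among called genes whose light libraries both lay on the same side of both dark libraries: the 3 highest and 3 lowest changes at 30 min and the 4 highest and 4 lowest at 1 h and 6 h in each tissue, the 4 and 4 of the difference between tissues at 1 h and 6 h, the 5 and 5 in darkness, the 3 and 3 of 6 h against 1 h, up to 4 called members of each list, and always HY5, CHS, ELIP1, PORA, HEMA1, IAA19, SAUR14 and LHY. After the largest changes were seen to lie in short and organelle genes, the same rule was also applied to nuclear coding genes with at least 500 nt of exons.

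The procedure was tested on simulated data made from the real dark means and the real spread between replicates. In hypocotyls at 1 h, 72 of 76 genes with an added change of 1.5 on the log2 scale were called, 53 of 55 with 2 and 69 of 69 with 3, with 3 false calls. For the difference between tissues the counts were 64 of 76, 52 of 55 and 69 of 69, with 2 false calls, and an unchanged comparison had 0. A changed list was called and 0 of 20 random lists were. The noise was drawn independently for each gene, so that these list counts do not test calls among genes whose levels vary together.

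Alternatives tried were a pseudocount of 0.1 FPKM, no filter, median-of-ratios scaling, quantile normalization, limma without the trend and each tissue fitted on its own. Others were replicate letters as a block, no minimum change, the authors' Cuffdiff values and fry. Lists were also tested without members taken by name as near-identical copies, and each replicate was left out in turn. Leaving out organelle genes and genes under 500 nt, and leaving out replicates for the lists, were added after the data were seen. The letters A and B were not used as pairs: the differences A minus B of the tissues at the same time correlated between -0.071 and 0.058 over 7 times, and those of pairs of times between -0.103 and 0.163 in cotyledons and between -0.112 and 0.12 in hypocotyls, over 21 pairs each.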

Results

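Gene expression was measured by poly(A) RNA-seq in seedlings of Arabidopsis thaliana, accession Col-0. They were grown in darkness for 3 days and then moved to simulated white light of 100 µmol m−2 s−1 from blue, red and low far-red LEDs. After 15 min, 30 min, 1 h, 3 h, 6 h or 12 h of light, and in darkness, the cotyledons together with the shoot apex were dissected from the hypocotyls, the embryonic stems. The 2 tissues at 7 times gave 14 groups of 2 biological replicates, named A and B, and 28 libraries in all. The deposited values were FPKM (fragments scaled to transcript length and to library size) for 33557 genes, and how Cuffnorm scaled the libraries is not given. Of these, 18678 genes with a mean of at least 1 FPKM over the libraries were tested with limma, and each value below is a mean ± SD of 2 libraries (n = 2). The p values of single genes rest on the spread between biological replicates, estimated from all 14 groups together. Those of gene lists compare the members with the other genes and depend strongly on the correlation assumed between genes. Fold changes are on the scale of log2(FPKM + 1), which understates the change of genes of low level.

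The sources used here give no read totals, but the steps between the lowest FPKM values gave each library's depth relative to the others. It ran from 0.615 in replicate A of cotyledons at 1 h to 1.72 in replicate B of hypocotyls at 1 h. In a library of average depth, 1 FPKM of a gene of 1500 nt corresponded to about 17.35 reads. In 17 nuclear genes under 500 nt that are named below, values scaled by this depth and between 1.5 and 5.5 times the gene's smallest value above 0 lay at a whole multiple of it in 98.3% of 58 cases. In 12 of the 17 the highest group mean was at most 5 such multiples, and in AT1G28990, AT1G15090 and AT3G61829 it was 1. The 2 replicates of a group had a Pearson correlation across genes of 0.965 to 0.985, which was the highest of either library with any other in 14 of 14 groups. Libraries of different tissues reached at most 0.755. The first principal component held 64.4% of the variance and separated the tissues. In hypocotyls it also moved with time, from 152 and 150 in the dark libraries to 34.9 and 38.5 at 12 h, toward the cotyledons. The second held 13.5% and rose with the time in light up to 6 h, with little further change at 12 h. The chloroplast-encoded genes took 1.57% to 20.5% of the summed FPKM in cotyledon libraries and 0.069% to 0.537% in hypocotyl libraries. At 1 h they took 20.5% in cotyledon replicate A and 4.23% in replicate B.

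**Figure D1:**
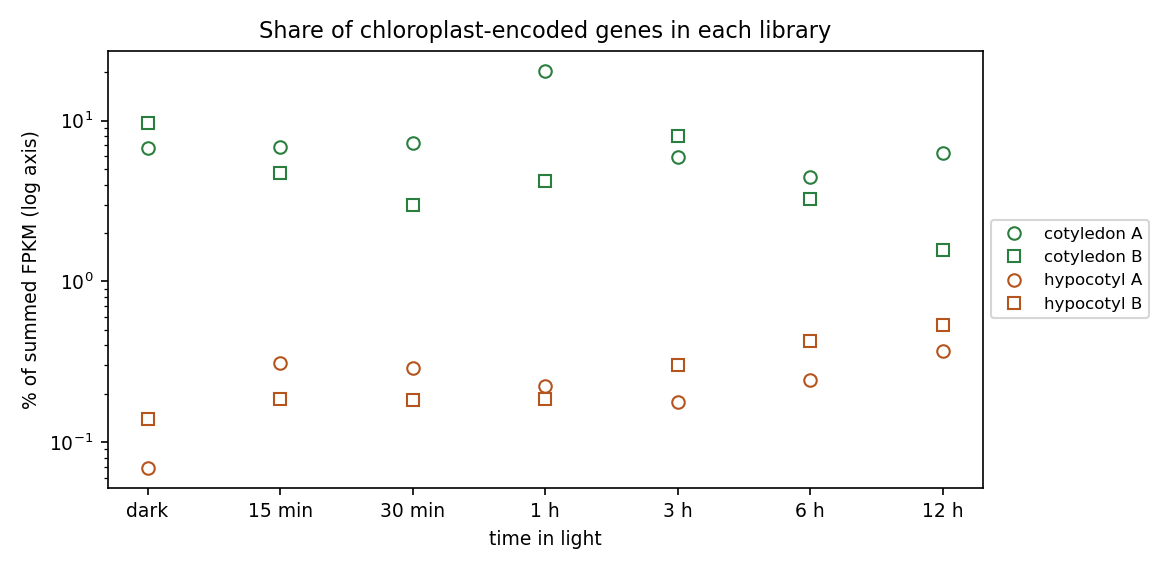
Share of the summed FPKM that fell on chloroplast-encoded genes, in percent on a log axis, in each of the 28 libraries by time in light. Circles are replicate A and squares replicate B. The cotyledon libraries lie between 1.57% and 20.5%, with replicates of 1 time up to 4.83 times apart, and the hypocotyl libraries between 0.069% and 0.537%.

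The series addressed how light responses differ between tissues during de-etiolation, the change from growth in darkness to growth in light. The number of genes that differed from darkness rose from 15 min to 6 h in cotyledons and to 12 h in hypocotyls. No dark libraries were matched to the later times, and in each tissue the 6 times share the same dark libraries. Changes given here for light may thus hold changes with age or time of day, which this design cannot tell apart. In cotyledons, limma called 158 genes at 15 min (56 higher and 102 lower), 630 at 30 min (318 and 312), 2115 at 1 h (1225 and 890), 4485 at 3 h (2440 and 2045), 5223 at 6 h (3163 and 2060) and 4359 at 12 h (2818 and 1541). In hypocotyls the counts were 186 at 15 min (71 higher and 115 lower), 673 at 30 min (329 and 344), 1542 at 1 h (913 and 629), 3955 at 3 h (2307 and 1648), 4880 at 6 h (2650 and 2230) and 5749 at 12 h (3101 and 2648). A call required an adjusted p under 0.05 and a change of at least 1 on the log2 scale. With a pseudocount of 0.1 FPKM in place of 1 FPKM, the hypocotyl split at 15 min became 124 higher and 100 lower. Under quantile normalization the cotyledon split became 2548 higher and 2305 lower at 6 h and 2293 and 1827 at 12 h, and in the authors' Cuffdiff values it was 2616 and 2197 and 2242 and 1599. The authors' deposited table of Cuffdiff results held 29764 genes, 15812 of them among those tested here, and its fold changes carry no pseudocount. There the same numerical limits on q and on the fold change gave 171, 636, 2019, 4194, 4813 and 3841 genes in cotyledons and 189, 684, 1541, 3766, 4598 and 5300 in hypocotyls, in the order of the times. Calls shared with limma numbered 132 at 15 min and 4253 at 6 h in cotyledons, and 154 and 4225 in hypocotyls. Every gene called in both had the same sign in both, over all 12 comparisons, which rest on the same libraries.

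**Figure D2:**
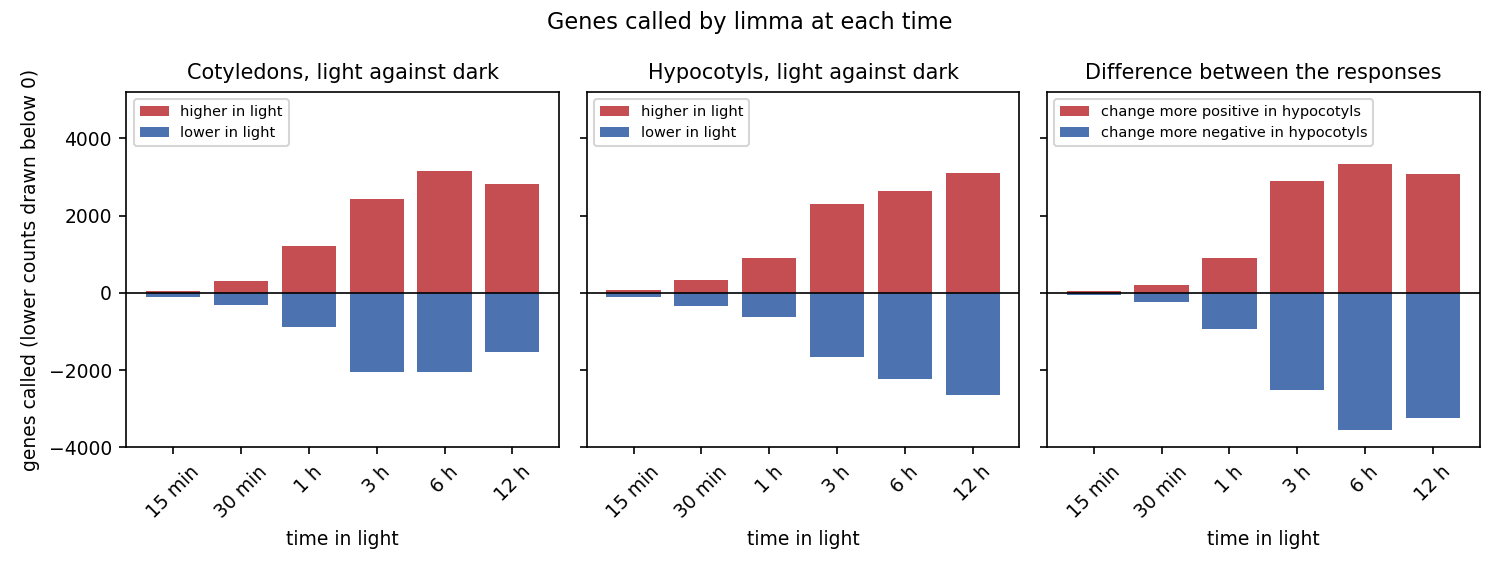
Number of genes called by limma at each time in light, with genes that were higher drawn above 0 and genes that were lower drawn below 0. The left and middle panels compare light with darkness in each tissue and reach 5223 genes in cotyledons at 6 h and 5749 in hypocotyls at 12 h. The right panel gives the genes whose change differed between the tissues, 6891 at 6 h.

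In cotyledons, regulators of the light response and clock genes were higher after 1 h of light, and genes of the shade response were lower. The regulators had a median log2 change of 2.73 at 1 h (quartiles 1.51 and 5.05). With an estimated correlation the 1 h call of the PIF and shade targets, of which 10 of 16 fell (median -2.03, adjusted p = 1.16e-05), ended (adjusted p = 0.107). By 6 h the genes of light harvesting, the photosystem cores, flavonoid synthesis, DNA replication and ribosome assembly were higher while those of lipid reserve use were lower. Each of these 6 list calls ended with an estimated correlation, with adjusted p values from 0.125 to 0.248. BBX32 (AT3G21150, chromosome 3, 7412445 to 7413727, minus strand, TAIR10.1), a B-box regulator of photomorphogenesis, went from 0.578 ± 0.171 FPKM in darkness to 64.4 ± 14.4 at 30 min and 341 ± 12.6 at 1 h. This was a log2 change of 7.76 (SE 0.152, adjusted p = 3.12e-18). PORA (AT5G54190, chromosome 5, 21990864 to 21992814, minus strand), the protochlorophyllide reductase of dark-grown seedlings, went from 1570 ± 296 FPKM to 3.52 ± 0.397 at 6 h, a log2 change of -8.43 (SE 0.204, adjusted p = 8.29e-17). Isocitrate lyase (ICL, AT3G21720), the glyoxylate cycle enzyme through which storage lipid is turned into sugar, went from 3852 ± 543 to 48.7 ± 4.59 FPKM at 6 h (log2 change -6.27, adjusted p = 6.66e-16).

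Among the largest changes in cotyledons at 30 min were AT3G12320, from 0.762 ± 0.259 to 74.4 ± 0.0969 FPKM, and the plastid sigma factor gene SIG5, from 2.11 ± 0.138 to 76.5 ± 8.99 FPKM. ATHB2, a homeodomain gene of the shade response, went from 30.9 ± 1.83 to 1.86 ± 0.772 FPKM, and AT3G21330 from 50.5 ± 4 to 2.95 ± 0.178 FPKM. At 1 h the early light-induced protein gene ELIP1 stood at 2293 ± 731 FPKM against 28.1 ± 18.3 in darkness. The thionin gene THI2.2 was at 150 ± 5.18 against 2.33 and 0.571 in the dark libraries. LHCB1.1, which encodes a chlorophyll-binding antenna protein, was at 687 ± 192 against 10.2 ± 1.07. The B-box gene BBX23 fell from 103 ± 23.4 to 2.19 ± 0.261 FPKM, AT5G53660 from 171 ± 13.8 to 4.38 ± 0.196 and RAV1, an AP2/B3 transcription factor gene, from 96.2 ± 8.4 to 2.2 ± 0.869. At 6 h LHCB1.1 reached 5185 ± 77.2 FPKM (log2 change 8.86, adjusted p = 1.09e-15), LHCB1.4 1435 ± 66.1 (13.7% shared) and THI2.2 486 ± 18.8. FLP1 fell to 0.316 ± 0.059 from 310 ± 42.2 and AT2G34020 to 0.316 ± 0.154 from 138 ± 1.58. Of LHCB1.1, 20.5% of the 50-nt stretches also occur in other annotated exons, so that its level is uncertain, and shares of this kind are given below for other genes. AT2G44130 fell from 26 ± 4.86 to 1.69 ± 2.35 FPKM at 30 min, but all of its 50-nt stretches (100%) lie in other annotated exons.

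The regulators of photomorphogenesis were 26 measured genes that include HY5, the BBX genes, ELIP1 and SIG5. At 30 min 19 rose and 3 fell, with a median log2 change of 1.78 (camera adjusted p = 2.15e-24 with a preset correlation and adjusted p = 0.00274 with an estimated one). HY5 (AT5G11260, chromosome 5, 3593335 to 3595073, minus strand), the bZIP factor that promotes photomorphogenesis, was at 82.5 ± 8.63 FPKM in darkness, 302 ± 11.9 at 1 h (adjusted p = 2.42e-11) and 55 ± 1.95 at 6 h (log2 change -0.57, adjusted p = 0.000126). Of 19 clock genes, 11 rose and 1 fell at 1 h, with a median of 2.38 (adjusted p = 2.06e-10, and adjusted p = 0.0108 with an estimated correlation). LNK1 went from 0.874 ± 0.317 to 83.1 ± 10.4 FPKM, GI from 1.96 ± 0.338 to 78.4 ± 1.07, and CCA1 from 5.67 ± 0.0508 to 166 ± 34.3. PRR9 went from 0.0248 ± 0.035 to 27 ± 2.44 and LHY from 17.2 ± 4.45 to 267 ± 92.4, with 31 ± 2.39 at 6 h. Of the 50-nt stretches of PRR9, 28.7% occur in other annotated exons. Of 16 photoreceptor and PIF genes, 4 rose and 3 fell at 6 h (median -0.17 but mean 0.51 and test upward, adjusted p = 0.959). PIF8 rose from 0.47 ± 0.127 to 70.1 ± 4.97 FPKM and PIF7 from 0.294 ± 0.211 to 20.9 ± 0.526. PHYA, the photoreceptor that is abundant in darkness, fell from 284 ± 26.4 to 32.7 ± 1.99, and PIF5 rose from 5.65 ± 0.0556 to 48.7 ± 1.18 at 1 h.

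Of the 18 light-harvesting genes, 13 rose at 1 h and 18 at 6 h, with a median of 3.46 at 6 h (adjusted p = 1.24e-11, and adjusted p = 0.177 with an estimated correlation). Of the 23 genes of the photosystem cores, 22 rose at 6 h (median 2.16, adjusted p = 6.58e-12, and adjusted p = 0.214 with an estimated correlation). Of the 24 chlorophyll synthesis genes, 14 rose and 2 fell at 6 h (median 1.19, adjusted p = 0.000172, and adjusted p = 0.492 with an estimated correlation). HEMA1, which acts at the first committed step of the pathway, rose from 126 ± 16.8 to 412 ± 4.99 FPKM (log2 change 1.71), which quantile normalization moved to 0.976. PORA, the member of this list that fell furthest, was at 732 ± 250 FPKM at 1 h. Its change of -1.13 went to -0.935 without dark replicate B and to -0.774 without replicate A of 1 h. Of the 13 carotenoid synthesis genes, 8 rose at 6 h (median 1.03, adjusted p = 6.18e-05, and adjusted p = 0.3 with an estimated correlation). BCH2 was at 94.5 ± 12 FPKM at 1 h against 4.41 ± 0.0826 and ZEP at 118 ± 7.31 at 6 h against 14.1 ± 2.69. Of the 17 flavonoid genes, 14 rose at 1 h and 16 at 6 h (median 3.91, adjusted p = 5.97e-10, and adjusted p = 0.125 with an estimated correlation). GSTF12 and LDOX, both of the anthocyanin branch, went from 0.225 ± 0.0765 to 170 ± 10.2 FPKM and from values listed at 0 in both dark libraries to 124 ± 4.9. CHS (AT5G13930), the first enzyme of the pathway, was at 10.7 and 47.7 FPKM in the dark libraries, at 228 ± 93 at 1 h and at 607 ± 3.82 at 6 h. The chloroplast share differed between the replicates of these cotyledon groups, by 20.5% against 4.23% at 1 h and 4.48% against 3.27% at 6 h.

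All 10 DNA replication genes rose in cotyledons at 6 h (median 1.36, adjusted p = 3.45e-05, and adjusted p = 0.191 with an estimated correlation). RNR2A went from 4.53 ± 0.304 to 34.6 ± 1.02 FPKM and PCNA1 from 9.89 ± 1.18 to 39.4 ± 3.81. TSO2 went from 34 ± 3.69 to 122 ± 5.81 FPKM and MCM3 from 5.45 ± 0.124 to 19.8 ± 0.37. Of 17 mitotic genes, 7 rose (median 0.87, adjusted p = 0.00328, and adjusted p = 0.357 with an estimated correlation). CYCA1;1 went from 5.02 ± 0.253 to 18.6 ± 1.22 FPKM. Of 21 genes of ribosome assembly and the nucleolus, 19 rose (median 1.53, adjusted p = 6.02e-10, and adjusted p = 0.248 with an estimated correlation). The fibrillarin gene FIB2 went from 15.5 ± 2.09 to 169 ± 4.11 FPKM, and NOP56 from 22.7 ± 1.23 to 148 ± 1.7. NOP58 went from 10.5 ± 1.69 to 85.5 ± 6.37 FPKM and the nucleolin gene NUC1 from 53.6 ± 10.3 to 300.5 ± 1.36. Of 9 type-A response regulator genes, which cytokinin induces, 6 rose at 6 h (median 1.71, adjusted p = 0.0205, and adjusted p = 0.214 with an estimated correlation). ARR16 went from 1.16 ± 1.01 to 18 ± 1.14 FPKM and ARR7 from 3.61 ± 0.517 to 32.6 ± 3.62. ARR6 (21.2% shared) went from 0.594 ± 0.481 to 9.54 ± 1.37 FPKM and ARR4 from 11.4 ± 3.13 to 71.7 ± 1.88. Of 11 genes of lipid reserve use, 8 fell at 6 h (median -1.89, adjusted p = 1.16e-05, and adjusted p = 0.214 with an estimated correlation). ICL fell the furthest, malate synthase (MLS) went from 202 ± 31.5 to 9.2 ± 0.956 FPKM and PCK1 from 754 ± 3.64 to 49 ± 0.125.

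Of 13 stomatal lineage genes, 7 rose in cotyledons at 6 h (median 1.01, adjusted p = 0.0376, and adjusted p = 0.334 with an estimated correlation). BASL went from 2.15 ± 0.349 to 12.7 ± 0.708 FPKM, POLAR (18% shared) from 7.06 ± 1.77 to 25.8 ± 2.18 and EPF2 from 8.6 ± 4.63 to 27.7 ± 4.37. The call of the list ended with a pseudocount of 0.1 FPKM (adjusted p = 0.191), without dark replicate B (0.0911) and without replicate B of 6 h (0.0514). Of 7 measured shoot meristem genes, 2 fell at 6 h (median -0.52, adjusted p = 0.209). AS1 (15% shared) went from 191 ± 28.3 to 70.5 ± 0.759 FPKM and STM from 10 ± 1.26 to 3.75 ± 1.07, with a change of STM of -0.993 without replicate B of 6 h. CUC1 was at 0.698 ± 0.628 FPKM in darkness and 2.64 ± 0.99 at 1 h. Its change of 1.12 became 0.738 without dark replicate B, 0.843 without replicate A of 1 h and 0.993 under quantile normalization. Of 12 vascular genes, 1 fell at 6 h (median 0.08 but test downward, adjusted p = 0.934), PP2-A1 (16% shared) from 82.8 ± 10.8 to 38 ± 3.13 FPKM, at -0.969 without dark replicate A. None of the 10 root genes passed the filter, and 1 of 13 seed storage genes did, with a change of -0.30 at 6 h (adjusted p = 0.782). Of 18 ethylene genes, 11 fell and 1 rose at 6 h (median -1.04, adjusted p = 0.000907, and adjusted p = 0.186 with an estimated correlation). HLS1, which shapes the apical hook, went from 32.5 ± 1.49 to 2.15 ± 0.0511 FPKM. EBF2 (16.6% shared) was lower at 1 h, at 15.1 ± 8.92 FPKM against 96.9 ± 4.37. Of 17 touch and rapid stress genes, 5 rose at 1 h (median 0.07, adjusted p = 0.184). DREB2A went from 3.08 ± 0.149 to 79 ± 5.34 FPKM and ZAT12 from 1.18 ± 0.371 to 23.3 ± 2.26, and XTH22 was at 110 ± 7.27 at 6 h against 7.75 ± 1.2. Of 9 heat shock genes, 3 rose and 1 fell at 1 h (median 0.48, adjusted p = 0.162). HSP90.1 went from 3.91 ± 0.347 to 18.8 ± 1.04 FPKM and HSFA2 from 1.37 ± 0.632 to 6.74 ± 1.62, and HSP22 was at 0.88 ± 0.864 at 6 h against 7.49 ± 1.48. Of 7 genes of primary wall cellulose synthesis, 2 rose at 6 h (median 0.31, adjusted p = 0.276). CESA5 went from 25.7 ± 1.9 to 83.2 ± 0.548 FPKM and CESA2 from 13.1 ± 1.13 to 37.2 ± 1.2. In cotyledons at 1 h and 6 h, each of these counts of members was equal when adjusted over the list alone.

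The rule for named genes also took genes, most of them short or chloroplast-encoded, with libraries at or near 0 in a group. At 30 min these were ATCG00410, listed at 0 in both light libraries against 261 ± 37.2 FPKM in darkness, and MIR390b (82.5 ± 59.2 in darkness) and AT3G61829 (15.3 ± 2.18), both also listed at 0 in light. AT5G64401 (100% shared) was taken too, with 75.3 ± 14 FPKM at 30 min against 3.78 ± 5.35. At 1 h they were AT3G27865, AT2G43138 and AT5G57181, listed at 0 in darkness, with 258 ± 113, 140 ± 80.4 and 103 ± 32.7 FPKM in light. AT2G34186 (100% shared) and AT4G25707 were lower in light, with 70.4 ± 38.3 and 40.8 ± 5.81 FPKM in darkness. At 6 h they were U60.2F and AT3G27865, with 580 ± 265 and 470 ± 357 FPKM and listed at 0 in darkness. ATCG00460 and ATCG00260 were at 496 ± 295 and 285 ± 40.6 FPKM in darkness and listed at 0 in light. Leaving out 1 library raised the adjusted p above 0.05 for ATCG00410 (to at most 0.0766), AT5G64401 (0.141), AT3G27865 at 1 h (0.16) and at 6 h (0.0956), AT2G43138 (0.146), AT2G34186 (0.0506), U60.2F (0.0719) and ATCG00460 (0.112).

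In hypocotyls, SAUR genes and PIF and shade target genes were lower from 15 min of light on and wall-loosening genes by 6 h. Regulators of photomorphogenesis were higher, and the genes of photosynthesis, photorespiration and flavonoid synthesis were higher by 6 h. With an estimated correlation, the 6 h calls of the wall-loosening, light-harvesting, photosystem core, Calvin cycle, photorespiration and flavonoid lists ended, with adjusted p values from 0.128 to 0.241. IAA19 (AT3G15540), an auxin-induced repressor gene of elongating hypocotyls, went from 575 ± 11.5 FPKM in darkness to 62.4 ± 6.98 at 1 h and 7.5 ± 0.904 at 6 h. The log2 change at 6 h was -6.09 (SE 0.191, adjusted p = 4.72e-16). HY5 went from 21.9 ± 0.023 to 358 ± 6.95 FPKM at 1 h (log2 change 3.97, adjusted p = 2.24e-16) and stood at 108 ± 5.08 at 6 h. ELIP1 (AT3G22840, chromosome 3, 8084405 to 8085669, minus strand) rose from 2.51 ± 0.518 to 404 ± 12.5 FPKM at 1 h and 758 ± 5.81 at 6 h. CHS was at 0.0633 ± 0.0895 FPKM in darkness, 8.4 ± 0.613 at 1 h and 250 ± 6.74 at 6 h (log2 change 7.89, adjusted p = 2.33e-09).

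Of the largest changes at 30 min, BBX30 (AT4G15248) was listed at 0 in both dark libraries and stood at 67.9 ± 0.42 FPKM, then at 126 ± 2.62 at 1 h. The transporter gene ABCI21 rose from 13.6 ± 2.53 to 455 ± 43.8 FPKM at 30 min. RTFL21, of the ROTUNDIFOLIA-like family of small polypeptides, fell from 160 ± 13.7 to 4.67 ± 0.3 and ATHB2 from 133 ± 9.12 to 5.05 ± 0.563. At 1 h SIG5 had gone from 0.31 ± 0.0352 to 138 ± 6.72 FPKM and PIL1 from 75.3 ± 6.82 to 1.51 ± 0.0394. The flavonoid gene F3H was at 137 ± 4.3 FPKM at 1 h against 0.288 ± 0.0346, but 84.5% of its 50-nt stretches occur in other annotated exons. At 6 h the cold-inducible gene KIN2 was at 344 ± 24.5 FPKM against 0.44 ± 0.622 in darkness and AT3G57020 at 319 ± 20.3 against 0.453 ± 0.488. MSRB9 (AT4G21850, chromosome 4, 11591116 to 11592425, minus strand), a methionine sulfoxide reductase gene, fell from 1774 ± 138 to 5.16 ± 0.283 FPKM (log2 change -8.17, adjusted p = 4.6e-12). P1R3 fell from 165 ± 4.34 to 0.155 ± 0.023. LHCB1.5 went from 4.99 ± 0.207 to 2896 ± 16.3 FPKM, and all of its 50-nt stretches (100%) also lie in other annotated exons.

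Of the 34 measured SAUR genes, auxin-induced genes of cell elongation, 28 fell in hypocotyls at 15 min, 29 at 30 min, 27 at 1 h and 32 at 6 h, and adjusted over the list alone 28, 30, 27 and 32 did. The median at 15 min was -2.06 (adjusted p = 3.59e-59, and adjusted p = 0.000761 with an estimated correlation). The median at 6 h was -4.08 (adjusted p = 1.96e-15, and adjusted p = 0.0318 with an estimated correlation). SAUR22 went from 213 ± 20.9 to 2.76 ± 0.409 FPKM, SAUR10 from 76.7 ± 6.91 to 0.796 ± 1.13 and SAUR7 (15% shared) from 56.6 ± 4.86 to 0.388 ± 0.315. SAUR19 fell from 160 ± 16 to 1.63 ± 0.466 FPKM, with 18.5% of its 50-nt stretches in other annotated exons. SAUR14 was at 55.3 ± 6.49, 62.5 ± 1.73 and 33.6 ± 6.34 FPKM in darkness, at 1 h and at 6 h. It passed no call at 1 h (adjusted p = 0.544) or at 6 h (log2 change -0.71), but fell at 15 min (-1.41), 30 min (-1.47), 3 h (-1.22) and 12 h (-1.06). Of 21 auxin response genes, 13 fell at 6 h (median -2.05, adjusted p = 8.89e-07, and adjusted p = 0.118 with an estimated correlation). IAA6 went from 90.6 ± 3.4 to 0.384 ± 0.0529 FPKM, and IAA29 was at 3.12 ± 0.483 at 1 h against 79.1 ± 3.44. In cotyledons IAA20 fell from 142.5 ± 11.9 to 4.39 ± 0.759 at 6 h. Of 16 PIF and shade target genes, 8 fell at 15 min, 8 also adjusted over the list alone (adjusted p = 3.7e-27, and adjusted p = 0.000805 with an estimated correlation), and 11 fell and 1 rose at 30 min. At 6 h 14 fell, with a median of -3.56 (adjusted p = 1.57e-08, and adjusted p = 0.031 with an estimated correlation). PAR1 fell from 66.4 ± 0.454 to 0.354 ± 0.107 FPKM and PAR2 from 174 ± 6.02 to 2.27 ± 0.159. In cotyledons 11 of the 16 fell at 6 h (adjusted p = 3.6e-07, and adjusted p = 0.0525 with an estimated correlation). XTH15, of whose 50-nt stretches 28.8% occur in other annotated exons, went from 2319 ± 558 to 39.6 ± 5.95 FPKM.

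Of 21 wall-loosening genes, 15 fell and 1 rose in hypocotyls at 6 h (median -2.55, adjusted p = 3.5e-06, and adjusted p = 0.241 with an estimated correlation). XTH19 (AT4G30290), a xyloglucan endotransglucosylase gene, went from 385 ± 15.6 to 1.68 ± 0.36 FPKM, XTH17 from 773 ± 4.83 to 5.86 ± 0.0558 and XTH18 from 355 ± 23.3 to 6.92 ± 0.74. Of 18 gibberellin genes, 4 rose and 6 fell at 6 h (median 0.17 but test downward, adjusted p = 0.948). GA2OX7, listed at 0 in both dark libraries, stood at 26 ± 0.402 FPKM and GA3OX2 at 21.6 ± 0.275 against 0.231 ± 0.0642. GA2OX1 rose from 1.77 ± 0.0196 to 61.5 ± 2.97 FPKM at 1 h, and in cotyledons GA2OX6 fell from 37.7 ± 2.19 to 0.959 ± 0.191 at 6 h. Of 14 brassinosteroid genes, 6 fell at 6 h (median -0.78, adjusted p = 0.0134, and adjusted p = 0.3 with an estimated correlation). SOB7 (23.8% shared) went from 85 ± 4.99 to 5.45 ± 0.15 FPKM and BR6OX1 from 32.8 ± 3.93 to 5.94 ± 0.859. BAS1 was lower at 1 h, at 6.25 ± 0.394 against 52.9 ± 3.23, and CPD in cotyledons at 6 h, at 59.5 ± 2.63 against 240 ± 17.9. ACS5, an ethylene synthesis gene, fell from 48.1 ± 0.344 to 0.0424 ± 0.0142 FPKM and ACS11 from 8.46 ± 1.42 to 1.01 ± 0.00383. The ethylene list had 5 of 18 lower at 6 h (median -0.59, adjusted p = 0.000438, and adjusted p = 0.169 with an estimated correlation).

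All 18 light-harvesting genes rose in hypocotyls at 6 h (median 5.12, adjusted p = 1.51e-14, and adjusted p = 0.128 with an estimated correlation). LHCB2.1 (21.9% shared) went from 0.249 ± 0.161 to 218.9 and 193.9 FPKM in the light libraries. All 23 of the photosystem cores rose too (median 3.65, adjusted p = 1.06e-17, and adjusted p = 0.141 with an estimated correlation). PSBS went from 10.1 ± 0.882 to 893 ± 46.6 FPKM and PSBO2 from 2.21 ± 0.314 to 143 ± 13.4. PSBR went from 29.9 ± 7.23 to 1141 ± 39.6 FPKM and PSBP1 from 28.2 ± 1.57 to 497 ± 14. All 18 Calvin cycle genes rose (median 4.84, adjusted p = 1.76e-13, and adjusted p = 0.158 with an estimated correlation). FBA1 went from 0.421 ± 0.0871 to 161 ± 12.5 FPKM and RCA from 26.4 ± 2.13 to 1089 ± 58.8. RBCS1B (13.9% shared) went from 0.958 ± 0.361 to 204 ± 11.8 FPKM and GAPB from 4.86 ± 0.754 to 229.5 ± 12.8. Of 11 photorespiration genes, 9 rose (median 3.31, adjusted p = 1.97e-06, and adjusted p = 0.178 with an estimated correlation). GOX1 went from 1.98 ± 0.675 to 166 ± 4.01 FPKM and SHM1 from 6.94 ± 0.304 to 314 ± 10.2. HPR1 went from 3.22 ± 1.01 to 198 ± 11.2 FPKM and AT1G23310 from 17.9 ± 0.749 to 428 ± 12.3. Of the chlorophyll synthesis genes, 18 rose and 1 fell (median 1.8, adjusted p = 1.68e-08, and adjusted p = 0.3 with an estimated correlation). CHLH went from 6.98 ± 0.00305 to 213 ± 13.8 FPKM, CRD1 from 15 ± 0.574 to 325 ± 8.74, HEMA1 from 16.3 ± 0.632 to 84.1 ± 1.6 and PORA from 10.6 ± 2.19 to 0.0615 ± 0.0368. GUN4 was at 108 ± 5.39 FPKM against 2.84 ± 0.213, with 71.9% of its 50-nt stretches in other annotated exons. Of the carotenoid genes 8 rose (median 2.38, adjusted p = 1.76e-06, and adjusted p = 0.214 with an estimated correlation). LUT5 went from 1.03 ± 0.392 to 37.1 ± 0.648 FPKM and BCH1 from 6.71 ± 1.11 to 70.5 ± 2.58. Of the flavonoid genes 13 rose (median 4.02, adjusted p = 7.07e-08, and adjusted p = 0.162 with an estimated correlation). PMDH2, of the lipid reserve list, rose from 2.39 ± 0.41 to 106 ± 9.15 FPKM, while that list had 1 member higher and 1 lower (median -0.12 and test downward but mean 0.22, adjusted p = 0.825). KAT1, a potassium channel gene of guard cells, fell from 21 ± 1.33 to 0.06 ± 0.0253 FPKM, HSP18.2 rose from 1.8 ± 1.16 to 12.4 ± 1.34 and TCH3 fell from 125 ± 17 to 15.5 ± 2.73. CYCD3;2 rose from 6.72 ± 0.577 to 25 ± 2.15 FPKM, CYCD3;3 rose from 4.19 ± 0.7 to 13.4 ± 0.365 and CYCA2;3 fell from 4.43 ± 0.371 to 1.23 ± 0.0392. Of the regulators of photomorphogenesis, 20 rose and 1 fell at 1 h (median 3.14, adjusted p = 2.1e-23, and adjusted p = 0.00294 with an estimated correlation). Of the clock genes 13 rose (median 1.69, adjusted p = 1.92e-14, and adjusted p = 0.00274 with an estimated correlation). LHY went from 13.1 ± 0.657 to 112 ± 10.6 FPKM and stood at 10.9 ± 0.704 at 6 h (adjusted p = 0.528). At 6 h each of these counts was equal adjusted over the list alone.

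The rule for named genes also took, in hypocotyls, the chloroplast genes ATCG00690, at 96.1 ± 6.17, 216 ± 28.3 and 253 ± 121 FPKM at 30 min, 1 h and 6 h. ATCG00110 was at 138 ± 21.3 at 1 h, and both were listed at 0 in darkness. The tRNA genes AT1G28990 (60.9% shared) and AT3G50835 (37.5% shared) were at 228 ± 47.1 and 209 ± 43.1 FPKM in darkness and listed at 0 at 30 min. AT1G15090 was at 116 ± 18 at 1 h and listed at 0 in darkness. RTFL18 was listed at 0 at 30 min and 1 h against 43.4 ± 30.5 FPKM in darkness. RTFL13 was at 721 ± 149 in darkness, 21.4 ± 7.03 at 1 h and 4.66 ± 6.59 at 6 h. Leaving out 1 library raised the adjusted p at 30 min to at most 0.0926 for ATCG00690 and 0.126 for RTFL18, and at 1 h to 0.0658 for AT1G15090 and 0.0713 for RTFL18. The call of RTFL13 at 1 h ended with a pseudocount of 0.1 FPKM (adjusted p = 0.112).

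**Figure D3:**
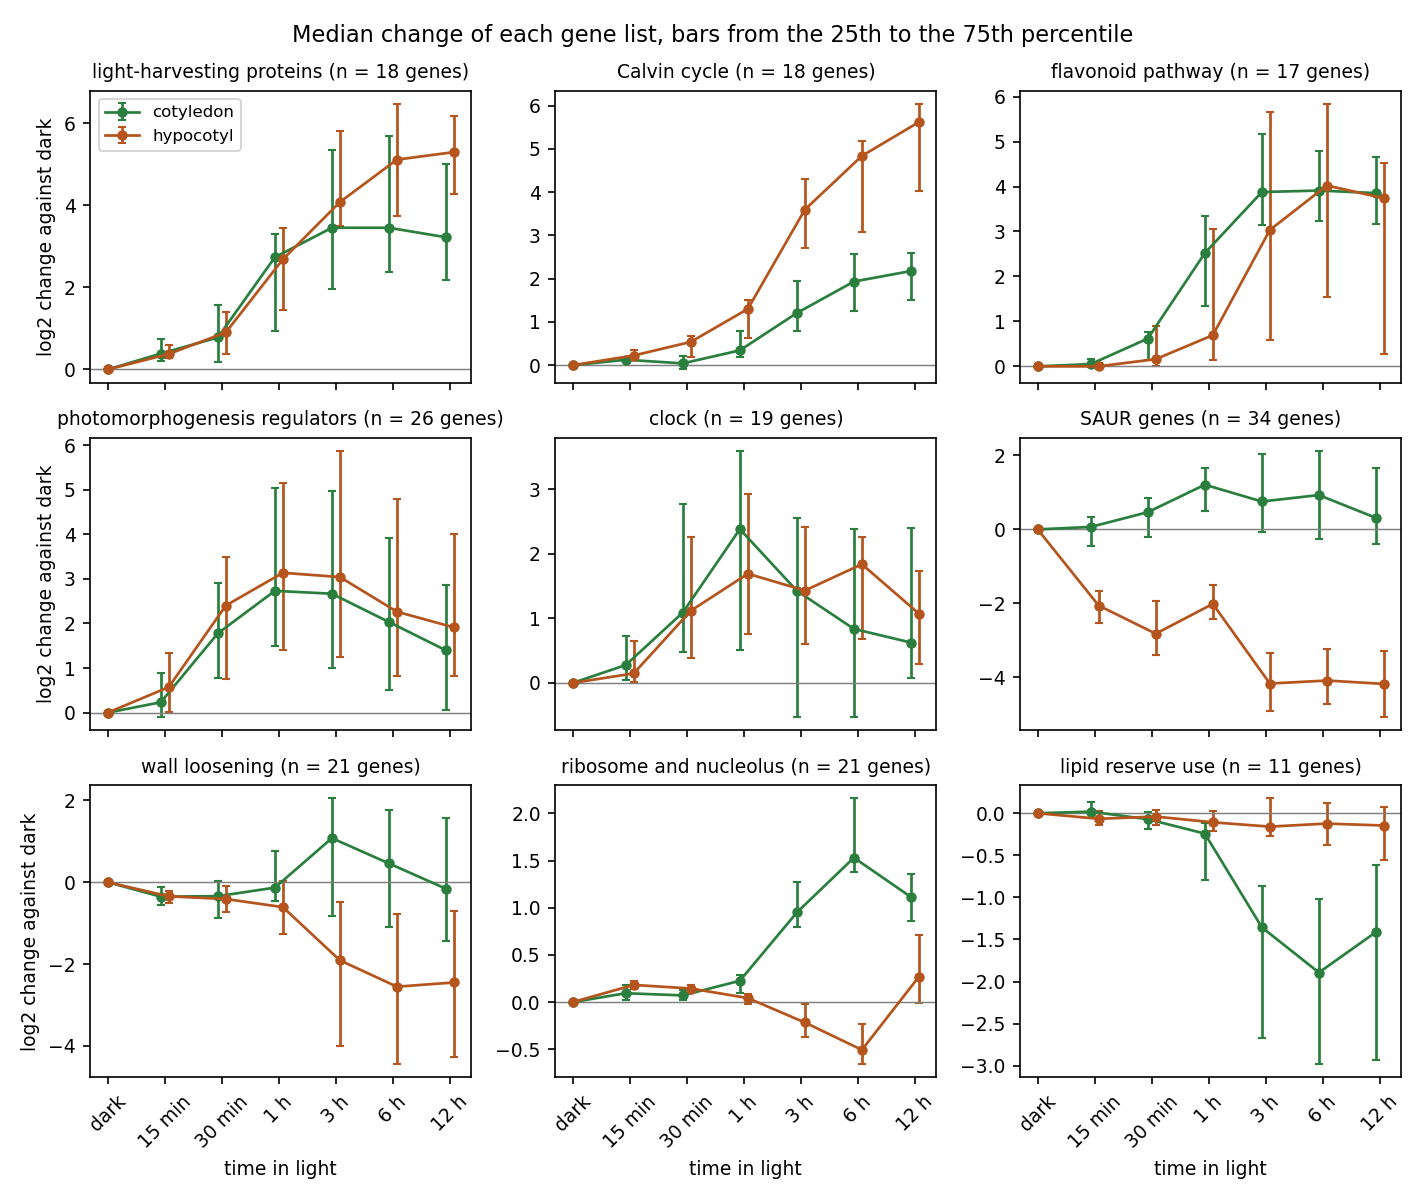
Median log2 change against darkness of 9 gene lists in cotyledons (green) and hypocotyls (orange) over 12 h of light, with bars from the 25th to the 75th percentile of the members. The bars show the spread between genes and not between replicates. At 6 h the SAUR median is 0.93 in cotyledons and -4.08 in hypocotyls, and the median of ribosome and nucleolus genes 1.53 and -0.51.

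The difference between the tissues was tested as the change in hypocotyls minus the change in cotyledons. At 1 h and 6 h it was negative for SAUR genes, and at 6 h it was positive for genes of photosynthesis and of lipid reserve use. The SAUR call was kept with an estimated correlation at 1 h (adjusted p = 0.0266) and ended at 6 h (adjusted p = 0.106), and with that correlation the calls of light harvesting (adjusted p = 0.717), the photosystem cores (0.521), the Calvin cycle (0.53) and lipid reserve use (0.448) ended. SAUR16 (AT4G38860, chromosome 4, 18130237 to 18131284, plus strand) rose in cotyledons from 1.92 ± 0.361 to 60.6 ± 1.6 FPKM at 6 h and fell in hypocotyls from 147 ± 7.08 to 4.9 ± 0.61. The difference was -9.05 (SE 0.332, adjusted p = 8.79e-14). FLA9, a fasciclin-like arabinogalactan protein gene, went from 55.7 ± 12.3 to 370 ± 6.81 FPKM in cotyledons and from 2726 ± 92.6 to 35.4 ± 3.02 in hypocotyls. The difference was -8.96 (SE 0.288, adjusted p = 1.18e-14). In the other direction, XTH31 (AT3G44990) went from 22.5 ± 2.86 to 1589 ± 84.7 FPKM in hypocotyls and was at 145 ± 14.1 and 81.6 ± 5.89 in cotyledons, a difference of 6.91 (adjusted p = 4.72e-14). Genes called for this difference numbered 94 at 15 min (43 positive and 51 negative), 450 at 30 min (215 and 235), 1849 at 1 h (907 and 942), 5419 at 3 h (2899 and 2520), 6891 at 6 h (3331 and 3560) and 6312 at 12 h (3074 and 3238). The split at 15 min became 59 positive and 30 negative with a pseudocount of 0.1 FPKM.

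At 1 h GNL (AT4G26150), a GATA factor gene of chloroplast development, was at 121 ± 28.5 FPKM in cotyledons against 2.04 ± 1.76 in darkness, and at 0.161 ± 0.166 in hypocotyls. The difference was -5.28 (adjusted p = 2.07e-08). RAV2 fell in cotyledons from 86.9 ± 1.65 to 13.6 ± 0.553 FPKM and rose in hypocotyls from 23.63 ± 2.48 to 101 ± 1.4 (difference 4.65). AT5G57770 (24.1% shared) was at 0.178 ± 0.251 FPKM in cotyledons and 21.4 ± 0.96 in hypocotyls at 1 h (difference 4.11). BBX23, which fell in cotyledons, was at 0.288 ± 0.407 FPKM in dark hypocotyls and listed at 0 there at 1 h and 6 h, so that its differences of 4.69 and 6.36 rest on the cotyledons. At 6 h KIN2 (difference 7.77) was at 66.7 ± 1.14 FPKM in cotyledons and 344 ± 24.5 in hypocotyls. HSFA6A, a heat stress transcription factor gene, was at 0.357 ± 0.212 and 76.9 ± 0.741 (difference 6.08). SAUR6 (AT2G21210) was at 99.6 ± 12.4 and 4.6 ± 0.0111 (difference -8.16), against 5.34 ± 2.77 and 95.7 ± 10.5 in darkness.

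Of the 34 SAUR genes, 20 rose and 1 fell in cotyledons at 1 h (median 1.21, adjusted p = 1.16e-05, and adjusted p = 0.213 with an estimated correlation). SAUR14 went from 12.9 ± 0.635 to 233 ± 15.4 FPKM, while IAA19 was at 7.71 ± 2.23 and 8.32 ± 2.08 (adjusted p = 0.719). In cotyledons at 6 h 17 rose and 2 fell (median 0.93, adjusted p = 0.0271, and adjusted p = 0.522 with an estimated correlation). The call ended without the members left out by name as near-identical copies (median 0.513, adjusted p = 0.0948). These were not screened by their shared stretches. The difference was negative for 30 of the 34 at 1 h, 31 adjusted over the list alone (median -3.30, adjusted p = 2.93e-23, and adjusted p = 0.0266 with an estimated correlation). At 6 h it was negative for 33, and for 33 adjusted over the list alone (median -5.11, adjusted p = 1.5e-14, and adjusted p = 0.106 with an estimated correlation). The differences at 6 h were negative for 16 of 21 auxin response genes (median -2.2, estimated adjusted p = 0.34) and 15 of 21 wall-loosening genes (median -3.13, estimated adjusted p = 0.521). They were also negative for all 10 DNA replication genes (median -2.11, estimated adjusted p = 0.448) and all 21 of ribosome assembly and the nucleolus (median -2.22, estimated adjusted p = 0.448). Positive differences were found for 8 of 11 genes of lipid reserve use (median 1.91, estimated adjusted p = 0.448) and 10 of 18 light-harvesting genes against 3 negative (median 1.4, estimated adjusted p = 0.717). They were also found for 19 of 23 of the photosystem cores (median 1.77, estimated adjusted p = 0.521) and 13 of 18 Calvin cycle genes (median 2.22, estimated adjusted p = 0.53). Each of these counts at 6 h was equal adjusted over the list alone, and with the preset correlation each of the 8 lists was called, the largest adjusted p being 0.00296 for light harvesting. The chloroplast-encoded share was 4.48% and 3.27% in the cotyledon libraries and 0.245% and 0.424% in the hypocotyl libraries at 6 h.

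The responses of the tissues rose and fell together for more genes than in opposite directions. At 6 h 1163 genes were higher in both tissues and 479 lower in both, against 449 and 246 for independent lists of the same sizes. Higher in cotyledons and lower in hypocotyls were 269 genes, against 377.6 for independent lists, and 123 the other way, against 292.3. The 392 genes with opposite changes also had a called difference, which opposite changes of at least 1 each nearly bring about by themselves. The correlation of the log2 changes across genes, which are not independent replicates, was 0.178 at 15 min, 0.482 at 1 h and 0.328 at 6 h. The tissues have separate dark libraries, so that this value holds no shared control.

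**Figure D4:**
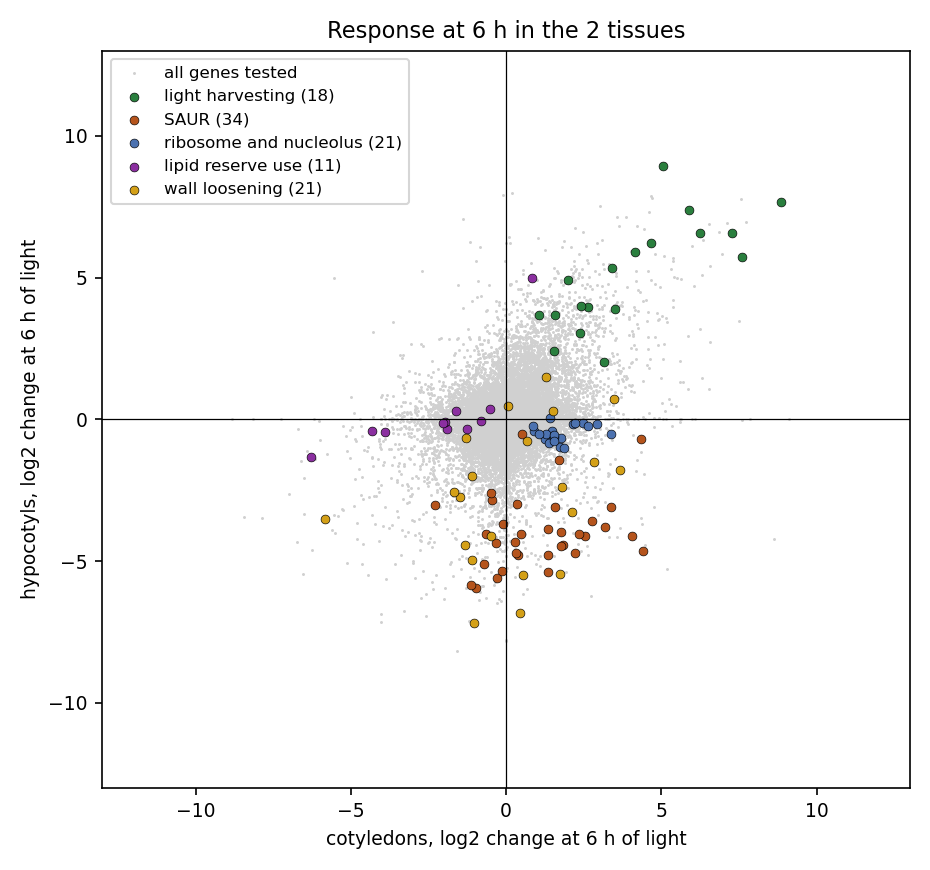
Log2 change at 6 h of light against darkness in cotyledons (horizontal axis) and hypocotyls (vertical axis) of the 18678 genes tested, with the members of 5 lists in colour. Light-harvesting genes lie to the upper right with medians of 3.46 and 5.12, and SAUR genes lie below 0 on the vertical axis, 32 of 34 called lower in hypocotyls.

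The rule also took, for the difference, genes with libraries at 0, most of them short or chloroplast-encoded. At 1 h these were SNOR30, ATCG00690, ATCG00110, AT4G25707, AT3G27865, RTFL18, AT1G28990 and AT5G10336 (67.8% shared), and RTFL13 among longer coding genes. At 6 h they were MIR156f (100% shared), ATCG00260, ATCG00690, MIR419, AT3G27865 and RTFL18. RTFL18 was at 43.4 ± 30.5 FPKM in dark hypocotyls and 35.4 ± 0.564 in cotyledons at 6 h and was listed at 0 in dark cotyledons and in hypocotyls at 6 h. Apart from ATCG00690 at 6 h, RTFL18 at both times and AT1G28990, each lost its call when 1 library was left out. The adjusted p values reached 0.179 for AT3G27865 at 1 h, 0.0828 for it at 6 h and 0.16 for MIR156f.

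In darkness SAUR and wall-loosening genes were higher in hypocotyls, and genes of photosynthesis were higher in cotyledons. With an estimated correlation these list calls ended (adjusted p = 0.223 for SAUR, light harvesting, the photosystem cores and the Calvin cycle, and 0.474 for wall loosening). TIP2;2, a tonoplast water channel gene, was at 1679 ± 259 FPKM in hypocotyls and 3 ± 0.587 in cotyledons, a log2 difference of 8.72 (SE 0.258, adjusted p = 1.1e-15). The Casparian strip gene CASP5 was at 1041 ± 46.4 against 1.22 ± 0.468 FPKM, XTH17 at 773 ± 4.83 against 0.91 ± 0.35 and ATPMEPCRD at 1168 ± 98.6 against 1.88 ± 0.532. Carbonic anhydrase CA2 was at 4.95 ± 2.41 FPKM in hypocotyls and 2571 ± 0.0141 in cotyledons (difference -8.82, adjusted p = 1.79e-17). The myrosinase gene TGG1 was at 1.6 ± 1.48 and 574 ± 76.1, and the germin-like gene GER3 at 11 ± 0.658 and 1802 ± 202. OEP6 and NdhO, both of chloroplast proteins, were at 656 ± 247 and 248 ± 37.7 FPKM in cotyledons and at 2.46 ± 0.508 and 0.347 ± 0.0966 in hypocotyls. In all, 8318 genes differed, 4365 higher in hypocotyls and 3953 higher in cotyledons.

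Of the lists, 31 of 34 SAUR genes were higher in dark hypocotyls (median 5.33, estimated adjusted p = 0.223), as were 13 of 21 wall-loosening genes (median 2.93, estimated adjusted p = 0.474). So were 13 of 21 auxin response genes (median 2.55, estimated adjusted p = 0.223) and 9 of 14 brassinosteroid genes (median 1.84, estimated adjusted p = 0.223). All 18 light-harvesting genes (median -4.28), all 23 of the photosystem cores (median -4.23), all 18 of the Calvin cycle (median -5.90) and 12 of 13 stomatal lineage genes (median -2.70) were higher in cotyledons, each with an estimated adjusted p of 0.223. With the preset correlation 16 of the 29 lists tested were called, among them each list named here, and 0 of the 16 with an estimated one. Each of these counts was equal adjusted over the list alone. The chloroplast-encoded share was 6.78% and 9.59% in dark cotyledons and 0.069% and 0.14% in dark hypocotyls. The rule for named genes took 5 chloroplast genes, ATCG00620, ATCG00400, ATCG00690, ATCG00010 and ATCG00110. They were listed at 0 in both dark hypocotyl libraries and at 2251 ± 78.3 to 4569 ± 2500 FPKM in dark cotyledons. RTFL13 was at 721 ± 149 FPKM in hypocotyls and listed at 0 in cotyledons, as was the rRNA gene AT3G41768, at 584 ± 332, with 94.3% of its 50-nt stretches in other annotated exons.

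Between 1 h and 6 h of light, flavonoid genes rose in both tissues, regulators of photomorphogenesis and clock genes fell in cotyledons, and wall-loosening genes fell in hypocotyls. With an estimated correlation these list calls ended, with adjusted p values from 0.212 to 0.496. Of the 17 flavonoid genes, 10 rose and 2 fell in cotyledons (median 1.06, adjusted p = 0.00631, and adjusted p = 0.496 with an estimated correlation). In hypocotyls 11 of them rose and 1 fell (median 1.26, adjusted p = 0.00012, and adjusted p = 0.295 with an estimated correlation). Of 21 wall-loosening genes 14 fell in hypocotyls (median -2.23, adjusted p = 2.91e-07, and adjusted p = 0.261 with an estimated correlation). In cotyledons LDOX went from 0.116 ± 0.0194 to 124 ± 4.9 FPKM (log2 change 6.80, adjusted p = 2.29e-18). DFR went from 0.0392 ± 0.0554 to 93.4 ± 5.94 and GSTF12 from 1.94 ± 1.95 to 170 ± 10.2. PORA fell from 732 ± 250 to 3.52 ± 0.397 FPKM (log2 change -7.30) and ICL from 1694 ± 238 to 48.7 ± 4.59. In hypocotyls AT3G44970 was listed at 0 at 1 h and stood at 118 ± 0.465 FPKM at 6 h. GSTF12 went from 0.0751 ± 0.0116 to 127 ± 8.74 and AT4G36220 from 1.02 ± 0.103 to 121 ± 3.46. MSRB9 fell from 1176 ± 6.06 to 5.16 ± 0.283 FPKM (log2 change -7.58, adjusted p = 2.69e-11). The arabinogalactan gene AGP22 fell from 1772 ± 48.6 to 20.5 ± 3.93 and XTH17 from 424 ± 35.8 to 5.86 ± 0.0558. In cotyledons 2074 genes were higher and 1259 lower at 6 h than at 1 h, and in hypocotyls 1955 and 1620.

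Of the regulators of photomorphogenesis, 13 fell and 3 rose in cotyledons from 1 h to 6 h (median -1.02, adjusted p = 9.77e-07, and adjusted p = 0.248 with an estimated correlation). Of the clock genes 11 fell and 1 rose (median -1.24, adjusted p = 1.79e-06, and adjusted p = 0.212 with an estimated correlation). In hypocotyls 7 of these regulators fell and 1 rose (median -0.26, adjusted p = 0.0681), and 6 clock genes fell and 2 rose (median -0.03, mean -0.36, adjusted p = 0.531). Of the SAUR genes 29 of 34 fell further in hypocotyls (median -2.24, adjusted p = 8.38e-11, and adjusted p = 0.248 with an estimated correlation). In cotyledons 7 rose and 6 fell (median -0.10, adjusted p = 0.884). Each of these counts was equal adjusted over the list alone. The rule also took genes listed at 0 in a group, in cotyledons AT3G50835, AT1G15090, AT2G43137, ATCG00610, MIR157a and AT3G25011, and in hypocotyls ATCG00110. The calls of ATCG00610, MIR157a and AT3G25011 ended when 1 library was left out, with adjusted p values up to 0.117, 0.0965 and 0.0658.

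**Figure D5:**
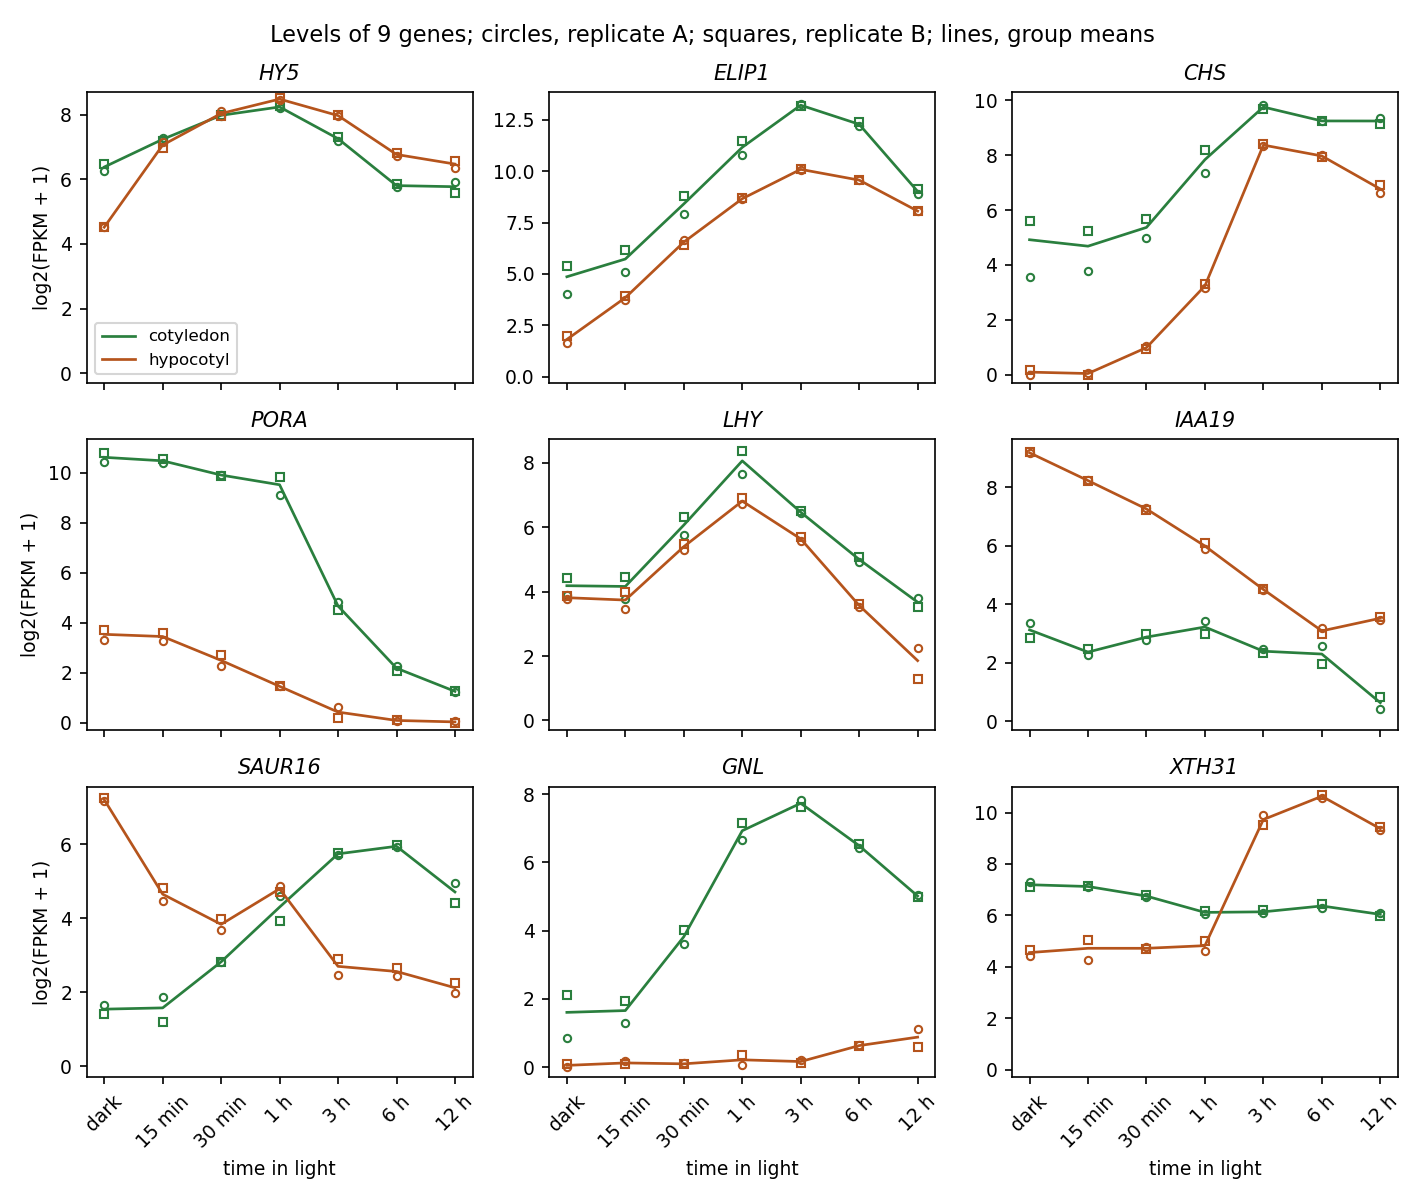
Levels of 9 named genes, as log2(FPKM + 1), in cotyledons (green) and hypocotyls (orange) over 12 h of light, with replicate A as circles, replicate B as squares and lines through the group means. HY5 peaks at 1 h in both tissues, at 302 and 358 FPKM, PORA falls from 1570 FPKM in dark cotyledons to 3.52 at 6 h, and SAUR16 falls in hypocotyls and rises in cotyledons.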

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

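The tests of carried-over cotyledon tissue, of copies in the cotyledon rise of SAUR genes and of short and chloroplast genes were chosen after the results were seen, and the other tests before. Each value that follows is the change in hypocotyls minus the change in cotyledons on the log2 scale, which limma tested as a difference between the tissues.

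Lists that differed between the tissues at 1 h, by their medians, were the photosystem cores (0.512), the Calvin cycle (0.548), flavonoid synthesis (-0.283), SAUR (-3.3), auxin response (-0.759), type-A response regulators (-0.541) and DNA replication (-0.431). At 6 h they were light harvesting (1.403), the photosystem cores (1.769), the Calvin cycle (2.222), chlorophyll synthesis (0.807), regulators of photomorphogenesis (0.481), SAUR (-5.107), auxin response (-2.201), brassinosteroid (-1.127), type-A response regulators (-1.42), wall loosening (-3.126), DNA replication (-2.106), ribosome assembly (-2.22), lipid reserve use (1.913) and photorespiration (1.32). With an estimated correlation, of these only SAUR at 1 h kept its call. With 1 replicate left out the calls at 1 h ended for the Calvin cycle (lowest median 0.333, adjusted p up to 0.181), flavonoid synthesis (-0.141, up to 0.184), type-A response regulators (-0.292, 0.0636) and DNA replication (-0.258, up to 0.0873). With a pseudocount of 0.1 FPKM those of flavonoid synthesis at 1 h (adjusted p = 0.303) and type-A response regulators at 6 h (adjusted p = 0.0801) ended.

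Genes that differed at 1 h were SNOR30 (7.941), ATCG00690 (7.572), ATCG00110 (6.565), AT4G25707 (5.926), AT3G27865 (-12.4), RTFL18 (-8.61), AT1G28990 (-7.823), AT5G10336 (-7.794), BBX23 (4.687), RAV2 (4.645), AT5G57770 (4.108), GNL (-5.28), SAUR16 (-5.132) and RTFL13 (-5.032). At 6 h they were MIR156f (10.512), ATCG00260 (8.153), ATCG00690 (7.984), MIR419 (7.952), AT3G27865 (-12.842), RTFL18 (-10.464), SAUR16 (-9.053), FLA9 (-8.957), KIN2 (7.768), XTH31 (6.908), BBX23 (6.358), HSFA6A (6.077) and SAUR6 (-8.161). Values of genes listed at 0 in a group depend on the pseudocount and are no measure of a fold.

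Of 34 SAUR genes 20 rose and 1 fell in cotyledons at 1 h and 17 rose and 2 fell at 6 h, list calls that ended with an estimated correlation (adjusted p = 0.213 and 0.522), while 32 fell in hypocotyls at 6 h. Reads shared between near-identical copies could mix their levels. The 21 members outside such copies, which were chosen by name, had a median difference of -4.53 at 6 h (quartiles -6.37 and -3.36), with 20 called. Of these members, 11 were called higher in cotyledons at 1 h (median 1.033, adjusted p = 0.00153). The difference and the rise at 1 h thus did not rest on the named copies alone. This split cannot decide on shared reads, since members were not screened by their shared stretches. The shared part was 0.6% in SAUR22, 2.6% in SAUR23 and 18.5% in SAUR19. For the rise at 6 h the list call ended without the named copies, which also made the list smaller. The 21 had a median of 0.513 (quartiles -0.31 and 2.21, adjusted p = 0.0948) against 0.927. Of the 21, 10 were called higher and 1 lower, against 17 and 2 of all 34. Whether the call depended on the copies or on the size of the list cannot be told from these values. Shared reads stay open for the difference and for the rise at both times. Under quantile normalization the cotyledon median at 1 h was 1.11, with 18 of 34 called higher. This argues against scaling as the source of the rise at 1 h, and the test did not cover 6 h. It is a weak test, since quantile normalization moved the median of all genes by at most 0.0966. Hypocotyl tissue among the cotyledon samples would raise other hypocotyl genes. But 105 such genes had a median cotyledon change of 0.12 at 6 h (quartiles -0.11 and 0.71) against 0.927 for the list. A different response of these genes in the 2 tissues may explain the difference, but not yet the cotyledon rise at 6 h. This is a hypothesis from the same data, with shared reads left open.

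Photosynthesis genes rose in hypocotyls at 6 h to a median of 15% of their cotyledon level. If tissue with the mix of the whole cotyledon samples were the source, every abundant cotyledon gene would be carried over. But 10 of 1507 genes at 100 FPKM or more in cotyledons, such as TGG1 (0.73%) and GASA6 (0.49%), lay below 1.5% in both hypocotyl libraries. All 41 members lay above it, the lowest at 2.73%. This bound rests on these 10 genes, while the 1st percentile of the 1507 was 3.44%. It also replaced a first one, on the share of such genes (0.66%), which had not decided. The values argue against carried-over tissue of that mix as the source of most of the signal of the median member. Tissue from a part of the cotyledons or apex without expression of the 10 genes is not excluded. Copies chosen by name, and members with over 30% of their 50-nt stretches in other annotated exons, were then left out. The 32 members that stayed, some with a smaller shared part, had a median change of 3.69, all called. This argues against reads of near-identical copies as the source of the rise in these 32. A response of the hypocotyl itself may explain the rise, as a hypothesis.

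Short and chloroplast genes were among the largest changes. Nuclear genes under 500 nt had a median SD between replicates 5.92 times that of longer genes matched on level (0.913 against 0.154), which is consistent with few reads behind them. In the 17 of them named here, 98.3% of the values at 2 to 5 times the smallest one lay at whole multiples of it after scaling by depth, against 58.1% in all such genes and 20% for values spread evenly, so that the values of most of the 17 may be counts of a few reads. The chloroplast share differed up to 4.83 times between the replicates of a cotyledon group, against 3.19 times between the highest and lowest group means, so that the share may follow the library more than the time in light. No biological explanation was tested for these genes.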

How the results depend on the processing

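Leaving out organelle and short genes, leaving out replicates for the lists, and every alternative for the lists in hypocotyls at 15 min and for 6 h against 1 h, were chosen after the data were seen. Counts of called genes stayed within 1.5 times the reported count under every alternative except no minimum change: 0.94 to 1.4 times with a pseudocount of 0.1 FPKM, 0.88 to 1.02 under quantile normalization, 0.88 to 1.08 in the authors' Cuffdiff values, and 0.85 to 1.27 with 1 replicate left out, where the lone library of a group is assumed to vary like the other groups. With no minimum change, which removes a limit, the counts in the order of the times were 582, 2260, 7409, 11591, 12306 and 11448 in cotyledons, 659, 2098, 4650, 9877, 11275 and 12635 in hypocotyls, 161, 959, 4974, 10361, 11820 and 11283 for the difference between tissues, 14532 in darkness, and 10366 and 9929 for 6 h against 1 h in cotyledons and hypocotyls. The split of the cotyledon genes for 6 h against 1 h, 2074 higher and 1259 lower, became 1587 and 1353 under quantile normalization. Of 348 list results, an estimated correlation ended 161 calls, fry ended 13 and added 70, the pseudocount ended 5 and added 4, quantile normalization ended 9 and added 9, median-of-ratios scaling ended 1 and lists without near-identical copies lost 2 and gained 1. The median-of-ratios factors ran only from 0.991 to 1.0204, so that this scaling could change little. Of 247 results of named genes, the pseudocount ended 6 calls, quantile normalization 3 and the block of letters 2. Leaving out 1 replicate had the largest effect on named genes, ending the call in 121 of 1096 refits, which concerned 30 of the 247 results, and adding 3. Among the lists it ended 43 calls in 1624 refits, which concerned 24 results, added 32 and changed 8 signs, 2 of them with the call ended. Quantile normalization moved the median of all genes by at most 0.0966 on the log2 scale. Medians near 0 of 2 lists changed sign in hypocotyls. At 30 min these were touch and rapid stress from -0.003 to 0.099 under quantile normalization and 0.003 to 0.135 with 1 replicate left out, and heat shock from 0.004 to -0.057 and -0.148 to 0.27, its call ending at -0.148 without dark replicate A (adjusted p = 0.0938). At 15 min touch and rapid stress went from -0.022 to 0.065 and -0.048 to 0.049, and heat shock from 0.051 to 0.019, with no call, and -0.202 to 0.303, its call ending at -0.202 without dark replicate A (adjusted p = 0.333) and without replicate B of 15 min (adjusted p = 0.0817). The cause was not tested.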

Other observations

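The genes here were chosen after their values were seen, from the 6 highest and 6 lowest changes at 15 min and 12 h among nuclear coding genes of at least 500 nt, and are not in every case the largest. No genes were chosen by their changes at 3 h. At 15 min of light, BBX30, listed at 0 in dark hypocotyls, was at 11.3 ± 2.12 FPKM there. HY5 already stood at 133 ± 12.2 FPKM in hypocotyls against 21.9 ± 0.023 in darkness (log2 change 2.54, adjusted p = 6.92e-12), and ABCI21 at 90.3 ± 0.651 against 13.6 ± 2.53. ATHB2 fell from 133 ± 9.12 to 10.7 ± 1.4 FPKM (log2 change -3.52) and SAUR22 from 213 ± 20.9 to 19.8 ± 1.92. In cotyledons AT3G12320 rose from 0.762 ± 0.259 to 18 ± 0.879 FPKM (log2 change 3.44, adjusted p = 1.07e-14), MAPKKK14 from 5.41 ± 0.721 to 34.9 ± 4.32 and HSP70 from 10 ± 2.51 to 39.5 ± 8.64, while RAV1 fell from 96.2 ± 8.4 to 11.9 ± 0.426 and PIL1 from 23.4 ± 2.02 to 3.34 ± 0.0264.

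At 12 h PORA stood at 1.38 ± 0.0543 FPKM in cotyledons (log2 change -9.35) and ICL at 13.5 ± 1.38 (log2 change -8.05), and FBA5, a fructose bisphosphate aldolase gene, at 376 ± 93.7 against 1.14 ± 0.65 in darkness. In hypocotyls LHCB1.5 (100% of its 50-nt stretches shared with other exons) went from 4.99 ± 0.207 to 3250 ± 614 FPKM and RBCS1B (13.9% shared) from 0.958 ± 0.361 to 570 ± 13.9. There THI1, of thiamine synthesis, rose from 4.28 ± 0.96 to 1270 ± 35.2 FPKM (log2 change 7.92, adjusted p = 5.91e-19) and FBA1 from 0.421 ± 0.0871 to 267 ± 13.4, while AGP22 fell from 2620 ± 225 to 3.64 ± 1.01 (log2 change -9.16) and MSRB9 from 1770 ± 138 to 3.27 ± 1.11.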
